A study of Mus musculus with 5 samples.

How the data were processed

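Single-cell RNA of mouse cardiac fibroblasts was measured in 5 libraries made with 10x Genomics 3′ version 2 chemistry, with 16000 cells loaded per library per the labels. The groups were healthy, day 7, day 14 and day 30 after infarction and Cthrc1 knockout at day 7, with 1 library each. Per the labels' protocols, tissue was digested with enzymes, red cells were lysed, cells were enriched with Feeder Removal MicroBeads and then sorted by flow cytometry. The matrices deposited by the authors hold transcript counts (UMIs) per gene and cell barcode. They were made with Cell Ranger 2.0 on mm10, per the submitters' processing notes, which also name Seurat 2.3.4. The values were whole numbers and no unit was contradicted. Gene identifiers were joined by Ensembl ID to the GENCODE vM21 annotation of GRCm38. Of 27998 identifiers, 27645 were found there and 26501 carried the same symbol.

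Barcodes were kept with at least 500 genes and at most 10% mitochondrial UMIs. This kept 36977 of 37452 barcodes and removed 13, 2, 0, 3 and 0 for few genes and 88, 252, 39, 61 and 27 for mitochondrial share, in the order healthy, day 7, day 14, day 30 and knockout. Doublet scores came from Scrublet as run in scanpy. Its own threshold called 0, 1, 5, 4 and 1 cells and had not worked, so the highest scores were removed at 0.8% per 1000 barcodes, which took 2318 cells. Counts were scaled to 10000 per cell for clustering, and 2000 variable genes, 30 components, 20 neighbours and Leiden clustering at resolution 0.6 gave 19 clusters. Cthrc1, mitochondrial, ribosomal protein, Xist and Y-linked genes were kept out of the clustering genes. Clusters were named from 18 marker sets where at least 3 markers were among the top 10 genes, more than for any other type, with a mean of at least 0.3 per 10000. That naming rule was chosen after the clusters were seen. All clusters not named as another cell type were taken as fibroblast-like.

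For each library, UMIs were summed over fibroblast-like cells and scaled to their total to give CPM. Log2 ratios used a pseudocount of 5 CPM, and printed ratios are of CPM without it. With 1 library per group no test between groups was possible. Intervals for CPM, ratios and shares are exact 95% intervals for counts, and those of list medians come from 200 Poisson draws. The comparisons were day 7, day 14 and day 30 against healthy, day 14 and day 30 against day 7, and knockout against day 7. Genes with a mean of at least 5 CPM were called measured, 9251 in number. List values are given relative to the median gene, a presentation chosen after a shift of the median gene in the knockout comparison was seen.

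The 21 gene lists were written before the data were examined, from general knowledge of the field. They cover collagens, matricellular genes, collagen processing and crosslinking, contractile, matrifibrocyte, resting fibroblast and activated scar genes, TGF-beta response and Wnt genes. The others are chemokines and inflammation, interferon response, cell cycle, immediate early and dissociation stress, proteases and inhibitors, glycolysis, oxidative phosphorylation, endoplasmic reticulum folding, lipid handling, ligands, mitochondrial transcripts and nuclear retained transcripts. Of 24 activated scar genes found in the files, 14 stand in another list. The counts for matricellular and matrifibrocyte genes are 4 of 25 and 4 of 17. For TGF-beta response and Wnt genes they are 3 of 25 and 3 of 26. Each list median was placed among 10000 random lists matched in 20 expression bins, as a description of these libraries, and called outside them below percentile 2.5 or above percentile 97.5. Members were counted at 1.5-fold from the median gene. Which lists lead the text was chosen after the values were seen. The list entries Cebpd and Trbc2 were not found by name and were not used here.

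Named genes followed a rule fixed beforehand. They had at least 100 CPM in the higher library and were not Xist, Y-linked, mitochondrial, ribosomal protein, haemoglobin or predicted genes. The highest 8 and lowest 8 were named for each infarct time against healthy, 5 and 5 for the later times against day 7, and 12 and 12 for the knockout. From each list outside the random range 3 members were named, and from the others the 2 most abundant. Not all of these members are printed. A gene that the rule names at day 14 is not reported here.

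Cells were thinned to 2000 UMIs at random (seed 7) to compare shares of cells with a Cthrc1 UMI. Cthrc1-positive cells had at least 2 UMIs after thinning and negative cells 0, and genes needed a mean of at least 0.1 thinned UMIs in the higher class. The 12 genes with the highest minimum log2 ratio over the 3 infarct libraries and the 8 with the lowest maximum were named, predicted genes included. Each processing choice was also run with alternatives of cell filter, doublet removal, scaling, pooling, pseudocount, expression minimum, thinning and clustering. Alternatives using adventitial Pi16-like cells alone, activated scar-like cells alone, no predicted genes in the clustering or no genes that separate healthy and day 30 from day 7 and day 14 were chosen after seeing the data.

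The steps were tested on Poisson counts drawn from the mean profile of the 5 libraries for 27998 genes. In each comparison 67, 67 and 66 genes were changed 1.5, 2 and 4-fold. Such counts hold no spread between libraries beyond counting error and no shared changes among genes. They check the working of the steps, not how the intervals and calls behave with real variation. Intervals covered the true ratio for 92.4% to 100% of changed genes. Of 100 unchanged lists, 3 were called at day 7, 8 at day 14, 6 at day 30, 4 for day 14 against day 7, 7 for day 30 against day 7 and 8 for the knockout. All 20 changed lists were called in each. For the Cthrc1-positive comparison, 30 of 30 tied genes ranked at the top. There the simulated negative cells had no Cthrc1 and the tied genes were raised 4-fold in every library, an easier setting than the data. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.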

Results

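Cardiac fibroblasts of C57BL/6 mice were profiled as single cells from uninjured hearts and from hearts collected 7, 14 and 30 days after myocardial infarction. These 4 libraries held cells sorted for GFP driven by the collagen gene Col1a1 and for lack of the endothelial protein CD31 and the leukocyte protein CD45. In another library, cells from mice lacking Cthrc1, taken 7 days after infarction, were sorted for the fibroblast surface marker mEFSK4 and for lack of the same 2 proteins. Genotype, reporter allele and sort marker therefore differ together between the knockout library and the day 7 library. Each group had 1 library, so no difference between conditions has a replicate check, and every interval given is a 95% interval that covers counting error only. Whether a library pools several mice is not given in the labels.

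The matrices held 7079 cell barcodes for the healthy heart, 10448 for day 7, 8337 for day 14, 6805 for day 30 and 4783 for the knockout. Their total counts were 36820862, 57097900, 59292690, 43779637 and 31595642 in the same order. After filtering and removal of presumed doublets, 34659 cells remained, of which 33429 were fibroblast-like. Pericyte-like, Schwann-like, mesothelial-like and macrophage-like clusters made up 2.99% of cells in the healthy library, 2.97% at day 7, 5.59% at day 14, 3.45% at day 30 and 2.23% in the knockout. Median depth per cell was 5212, 4963, 6836.5, 6243.5 and 5288 transcript counts (UMIs) in the order healthy, day 7, day 14, day 30 and knockout. Ribosomal protein genes took 15.9%, 15.4%, 12.6% and 16.02% of the counts in the GFP libraries and 20.7% in the knockout library, which stood apart from the others. Mitochondrial transcripts took 2.99%, 2.85%, 1.97%, 2.69% and 3.02%.

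Cthrc1, the gene removed in the knockout and a secreted glycoprotein made by fibroblasts in injured tissue, was measured first in every library. The gene (ENSMUSG00000054196) lies on the plus strand of chromosome 15 at 39076932 to 39087121 of GRCm38. Its level in fibroblast-like cells was 4.48 CPM (3.80 to 5.26) in the healthy library, 337 (332 to 342) at day 7, 827 (819 to 835) at day 14 and 86.9 (84.0 to 89.8) at day 30. The knockout library held 41.0 CPM (38.7 to 43.4), from 1178 counted transcripts. A 3′ tag can lie outside the deleted part of a gene, so these counts do not check the knockout. Relative to the healthy library, Cthrc1 was 75.2-fold higher (64.0 to 88.9) at day 7, 184-fold higher (157 to 218) at day 14 and 19.4-fold higher (16.4 to 23.0) at day 30. It was 8.23-fold lower (7.76 to 8.74) in the knockout library than at day 7. The ratio was 0.122 (0.114 to 0.129), and 0.196 under median-of-ratios scaling. Within cells of the adventitial Pi16-like class alone, the ratios to healthy were 4.69 at day 7, 12.6 at day 14 and 3.33 at day 30, a comparison chosen after the data were seen. No background was subtracted. The day 7 level in these cells, 28.1 CPM (23.6 to 33.3), lay below the 63.5 CPM (47.6 to 83.1) of pericyte-like cells, taken as a guide to background. Interstitial resting-like cells of that library held only 19.3 CPM (17.4 to 21.4), so evenly spread free RNA does not give the pericyte-like level. The adventitial level lay above 19.3 CPM. Evenly spread free RNA can therefore give much of that day 7 level, but not all of it. At day 14 the adventitial level was 75.3 CPM (65.6 to 85.9) against 43.8 (28.3 to 64.7) in pericyte-like cells. At day 30 it was 19.98 (15.8 to 25.0) against 0 with an upper limit of 58.1, from too few pericyte-like cells to set a background. The unnamed cluster 1 of the day 30 library (3307 cells) stood at 4.85 CPM, so evenly spread free RNA does not give all of the adventitial level.

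Cells holding Cthrc1 RNA were counted after each cell was thinned to 2000 UMIs. In the healthy library 0.654% of fibroblast-like cells (0.468 to 0.890) had a Cthrc1 UMI, against 13.5% (12.8 to 14.2) at day 7, 36.3% (35.2 to 37.4) at day 14, 6.75% (6.13 to 7.41) at day 30 and 3.44% (2.93 to 4.02) in the knockout. Thinning left out 281, 610, 61, 144 and 0 shallower cells in that order, and the unthinned shares were 1.67%, 18.2%, 51.8%, 11.9% and 10.4%. Pericyte-like cells served as a guide to free RNA in the droplets, an imperfect one at day 7, as the levels above show. A Cthrc1 UMI was found in 0 of 68 such cells in the healthy library, 7 of 164 (4.27%) at day 7 and 9 of 122 (7.38%) at day 14. At day 30 it was found in 0 of 13, and in the knockout in 0 of 5. Median depths of pericyte-like cells were 2330, 3566.5, 4034, 4249 and 4864 UMIs. The 0 counts allow shares of up to 5.28%, 24.7% and 52.2%, so these cells are too few to set a background in the healthy, day 30 and knockout libraries, and the healthy level in every ratio above is not corrected for background. Within the day 30 library Cthrc1 was at 393 CPM in cluster 10, led by Comp and Angptl7 (960 cells), and at 4.85 CPM in cluster 1 (3307 cells), a gap that RNA spread evenly over droplets does not give.

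**Figure D1:**
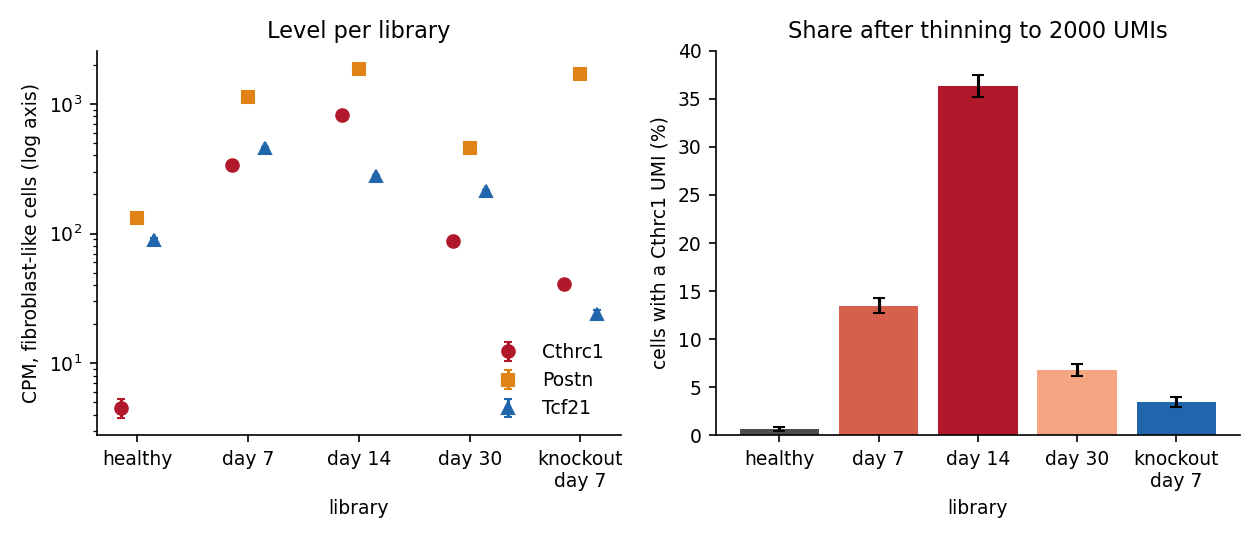
Cthrc1 in the 5 libraries, as CPM summed over fibroblast-like cells (logarithmic axis) and as the percentage of fibroblast-like cells with a Cthrc1 UMI after thinning to 2000 UMIs. Bars are 95% intervals for counting error; the highest values are those of day 14, 827 CPM and 36.3%.

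The time course asked which programs differ in fibroblasts as an infarct heals. At day 7 the Wnt modulator Sfrp2 was 11.4-fold higher (10.9 to 11.95) than in the healthy library, the matricellular gene Postn 8.64-fold (8.37 to 8.91), the collagen crosslinking enzyme gene Lox 8.58-fold (7.86 to 9.37) and the growth factor gene Ptn 6.06-fold (5.81 to 6.32). Tcf21, a transcription factor of the cardiac fibroblast lineage, stood at 458 CPM against 88.6 in the healthy library, and Col1a1 at 2608 against 933. Genes of the activated scar fibroblast list were higher as a group, with 19 of 23 measured members more than 1.5-fold above the median gene. The list median was 1.51 log2 units (1.46 to 1.56) above the median gene, at percentile 100 of matched random lists, and Ddah1, which breaks down an inhibitor of nitric oxide synthesis, was at 96.7 CPM against 5.50. The median was 0.43 in adventitial Pi16-like cells alone and 0.95 with a pseudocount of 20 CPM. This list was written from general knowledge of the field, which may include work on these samples, so its direction is not independent evidence.

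Among matrix groups at day 7, 11 of 19 collagens and 12 of 25 matricellular genes were more than 1.5-fold above the median gene and 0 of either were as far below. Their medians were 0.63 and 0.46 log2 units, both at percentile 100. Col8a2 was at 27.3 CPM against 3.05, Col12a1 at 41.5 against 9.33, Tnc at 23.8 against 1.41 and Thbs4 at 64.9 against 4.78. Collagen processing genes had a median of 0.31 (percentile 99.99), with P4ha3 at 14.0 against 0.448 CPM and Loxl3 at 72.0 against 19.6. Matrifibrocyte genes were at 0.32 (percentile 99.9), TGF-beta response genes at 0.28 (percentile 99.99) with Tgfb1 at 72.2 against 12.6 CPM, and Wnt genes at 0.37 (percentile 99.9) with Wisp1 at 23.8 against 2.003. Contractile genes were at 0.11 (percentile 99.3), with 4 of 17 above 1.5-fold, but at -0.20 in adventitial Pi16-like cells alone. Tagln was at 90.2 against 22.1 CPM and Acta2 at 117 against 41.6, and the smooth muscle marker set, which contains both, summed to 265 against 92.3 CPM in the same cells.

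Inflammatory genes were higher at day 7, with a list median of 0.72 (percentile 100) and 14 of 24 members more than 1.5-fold above the median gene. The acute phase gene Saa3 was at 59.8 CPM against 6.88, and the complement genes C1s1 and C4b at 197 against 61.2 and 63.3 against 18.8. Proteases and their inhibitors had a median of 0.11 (percentile 99.1), with Mmp14 at 184 against 69.9 CPM and Adamts4 at 48.3 against 13.8. Ligands of the cytokine and growth factor list were at 0.24 (percentile 98.5), with Mdk at 177 against 96.1 CPM. Immediate early and dissociation stress genes were at 0.07 (percentile 99.97), with Socs3 at 819 against 185 CPM and Hspa1a at 411 against 141. Oxidative phosphorylation genes were lower, at -0.42 (percentile 0.02), with Cycs at 94.8 against 169.8 CPM. Endoplasmic reticulum folding genes were also lower, at -0.35 (percentile 1.69), with Manf at 319.8 against 568 CPM. Medians inside the range of random lists were 0.19 for cell cycle, 0.13 for interferon response, 0.04 for glycolysis, -0.22 for resting fibroblast genes, -0.16 for lipid handling, -0.34 for mitochondrial transcripts and -0.41 for nuclear retained transcripts.

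The hormone-sensitive lipase gene Lipe was 11.98-fold higher (10.9 to 13.2), Scand1 9.50-fold (8.72 to 10.4) and the translation initiation factor gene Eif3f 6.89-fold (6.62 to 7.17). Lower in the day 7 library were AY036118 (3.13-fold, 2.97 to 3.30), Wdr89 (3.08-fold, 3.00 to 3.17), the cytochrome oxidase copper chaperone gene Cox17 (2.43-fold, 2.33 to 2.54) and the mTORC1 inhibitor gene Ddit4 (2.43-fold, 2.2998 to 2.56). Also lower were Sdf2l1 (2.25-fold, 2.15 to 2.37), Atp5k (2.17-fold, 2.10 to 2.23), the glucocorticoid-induced gene Tsc22d3 (2.10-fold, 2.05 to 2.16) and the nuclear RNA Malat1, at 21323 against 44847 CPM. Scand1 and Eif3f were at 157 and 600.2 CPM at day 14, and at 12.6 and 64.6 CPM at day 30. Wdr89 was at 153 CPM at day 14 and 333 at day 30.

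At day 14 the fibroblast-like cells were marked by cartilage-like and scar matrix genes. Sfrp2 stood at 3425 CPM against 56.3 in the healthy library, a 60.8-fold ratio (58.1 to 63.7), and Comp, the cartilage oligomeric matrix protein gene, at 1534 against 51.0 (30.1-fold, 28.7 to 31.6). Ddah1 was 44.5-fold higher (38.5 to 51.7), Thbs4 24.2-fold (20.7 to 28.5), the collagen-binding proteoglycan gene Fmod 14.5-fold (13.3 to 15.9) and Postn 14.3-fold (13.8 to 14.7). Matrifibrocyte and cartilage-like genes had a median of 1.83 log2 units above the median gene (1.76 to 1.90, percentile 100), with 11 of 14 members more than 1.5-fold above it. The activated scar list was at 1.85 (1.81 to 1.90, percentile 100), with 19 of 23 members above 1.5-fold. In adventitial Pi16-like cells alone these medians were 1.13 and 0.98, and the activated scar median was 1.11 without the genes that separate healthy and day 30 from day 7 and day 14. Those genes were picked by a gap that includes day 14 against healthy, so leaving them out tends to lower this median.

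Other matrix groups at day 14 were also higher than in the healthy library. Matricellular genes had a median of 1.13 (percentile 100, 17 of 25 above 1.5-fold and 3 below), with Ltbp2 at 121 CPM against 14.1. Collagens were at 0.56 (percentile 99.98, 9 of 19 above and 3 below), with Col8a2 at 56.4 against 3.05 CPM and Col11a1 at 21.1 against 0.747. The collagen median was -0.24 in adventitial Pi16-like cells alone, and -0.16 over all fibroblast-like cells without the genes that separate healthy and day 30 from day 7 and day 14. The value of -0.16 is no independent check, since the genes left out were picked by this same difference. Processing and crosslinking genes were at 0.44 (percentile 99.97), with P4ha3 at 31.4 against 0.448 CPM and Lox at 153 against 16.3. TGF-beta response genes were at 0.69 (percentile 100), with Tgfb1 at 112 against 12.6 CPM, Tgfb3 at 228 against 39.4 and Ctgf at 341 against 71.9. Wnt genes were at 0.51 (percentile 99.9), with Frzb at 358 against 53.6 CPM and Wisp2 at 952 against 169.5. Endoplasmic reticulum folding genes were at 0.27 (percentile 99.9), with the chaperone genes Hspa5 at 1983 against 709 CPM and Pdia4 at 212 against 73.8.

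Inflammatory genes at day 14 were at 0.39 (percentile 99.97), with the chemokine gene Cxcl2 at 70.6 against 7.44 CPM and Il6 at 184 against 48.7. Glycolysis genes were at 0.41 (percentile 99.8), with the lactate transporter gene Slc16a3 at 34.8 against 10.6 CPM. Immediate early genes, which tissue dissociation can induce, were at 0.65 (percentile 99.99, 14 of 24 above 1.5-fold), with Egr2 at 134 against 24.04 CPM and Dusp1 at 2995 against 975. Resting fibroblast genes were lower, at -0.35 (percentile 0), with 10 of 24 members more than 1.5-fold below the median gene and 4 above. In adventitial Pi16-like cells alone this median was 0.18. Among its members, Inmt was at 38.8 CPM against 134, the lipoprotein lipase gene Lpl at 327 against 942 and Abca8a at 157 against 384. Lipid handling genes were at -0.30 (percentile 0.265), with Scd1 at 34.1 against 77.0 CPM, and oxidative phosphorylation genes at -0.18 (percentile 0.72), with Atp5g3 at 153 against 278 CPM. Mitochondrial transcripts were at -0.56 (percentile 0), with mt-Nd3 at 109.8 against 389 CPM, and nuclear retained transcripts at -0.40 (percentile 2.24). Medians inside the random range were 0.14 for contractile genes, 0.18 for proteases, 0.16 for interferon response, -0.15 for cell cycle and -0.03 for ligands.

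Among genes with at least 100 CPM in the higher library, the lowest ratios at day 14 under the naming rule were those of AY036118 (9.04-fold lower, 8.36 to 9.79), the neuropeptide gene Nmb (3.65-fold, 3.46 to 3.85), Inmt (3.45-fold, 3.27 to 3.63) and Cox17 (2.99-fold, 2.86 to 3.13). They were followed by Wdr89 (2.96-fold, 2.88 to 3.04), the aggrecanase gene Adamts5 (2.88-fold, 2.80 to 2.97), Lpl (2.88-fold, 2.83 to 2.94) and the ferritin receptor gene Scara5 (2.79-fold, 2.66 to 2.92). Macrophage markers summed to 37.6 CPM in the fibroblast-like cells of this library against 12.98 in the healthy library.

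At day 30 Comp was at 797 CPM against 51.0 in the healthy library (15.6-fold, 14.9 to 16.4), Fmod 8.27-fold higher (7.56 to 9.08), Sfrp2 3.61-fold (3.43 to 3.80) and Postn 3.48-fold (3.36 to 3.59). Matrifibrocyte genes had a median of 1.15 log2 units above the median gene (1.07 to 1.21, percentile 100), with 10 of 14 members above 1.5-fold. The activated scar list was at 0.87 (0.85 to 0.92, percentile 100), with 14 of 23 above. With no minimum expression level these medians were 0.64 and 0.82. Lipe had the highest ratio of the named genes, 33.6-fold (30.5 to 37.1), and the scaffold protein gene Grip2 was 6.39-fold higher (5.98 to 6.85).

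Collagens were lower at day 30 than in the healthy library, with a median of -0.16 (percentile 0.035), 4 of 19 above 1.5-fold and 3 below. Col15a1 was at 380.3 CPM against 643, Col5a3 at 61.9 against 99.1 and Col1a1 at 807 against 933. Matricellular genes remained higher, at 0.33 (percentile 100), with Thbs4 at 62.1 CPM against 4.78 and Ltbp2 at 70.8 against 14.1. Crosslinking genes were at 0.16 (percentile 99.5), with Lox at 39.4 against 16.3 CPM. TGF-beta response genes were at 0.32 (percentile 100), with Bhlhe40 at 130.2 against 50.4 CPM, and Wnt genes at 0.16 (percentile 97.9), although without a minimum expression level the Wnt median was -0.0084. Resting fibroblast genes were higher, at 0.14 (percentile 98.9), with 2 of 24 members above 1.5-fold and 1 below. Tcf21 was at 213 CPM against 88.6 and Smoc2 at 1032 against 533.

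Inflammatory genes at day 30 were at 0.34 (percentile 100), with C1s1 at 123 against 61.2 CPM and Icam1 at 63.2 against 32.9. Stress genes were at 0.45 (percentile 100), with the heat shock gene Hspa1a 3.56-fold higher (3.45 to 3.68) and Socs3 3.35-fold (3.26 to 3.45). Glycolysis genes were at 0.30 (percentile 99.99), with the hexokinase gene Hk2 at 159 against 82.6 CPM. Lower groups were lipid handling at -0.19 (percentile 0.135), oxidative phosphorylation at -0.10 (percentile 1.53) and nuclear retained transcripts at -0.20 (percentile 2.33). Medians inside the random range were 0.12 for contractile genes, 0.01 for proteases, 0.03 for interferon response, -0.08 for cell cycle, 0.08 for ligands, -0.04 for folding genes and -0.07 for mitochondrial transcripts. Among genes with at least 100 CPM in the higher library, the naming rule gave the lowest ratios for Ddit4 (2.14-fold lower, 2.03 to 2.27), AY036118 (2.13-fold, 2.02 to 2.24), Lpl (1.85-fold, 1.82 to 1.88), Col15a1 (1.69-fold, 1.66 to 1.73) and Emp2 (1.68-fold, 1.60 to 1.76). Phlda1 (1.64-fold, 1.61 to 1.67), the laminin gene Lamb1 (1.64-fold, 1.59 to 1.69) and Scara5 (1.62-fold, 1.55 to 1.69) came next.

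**Figure D2:**
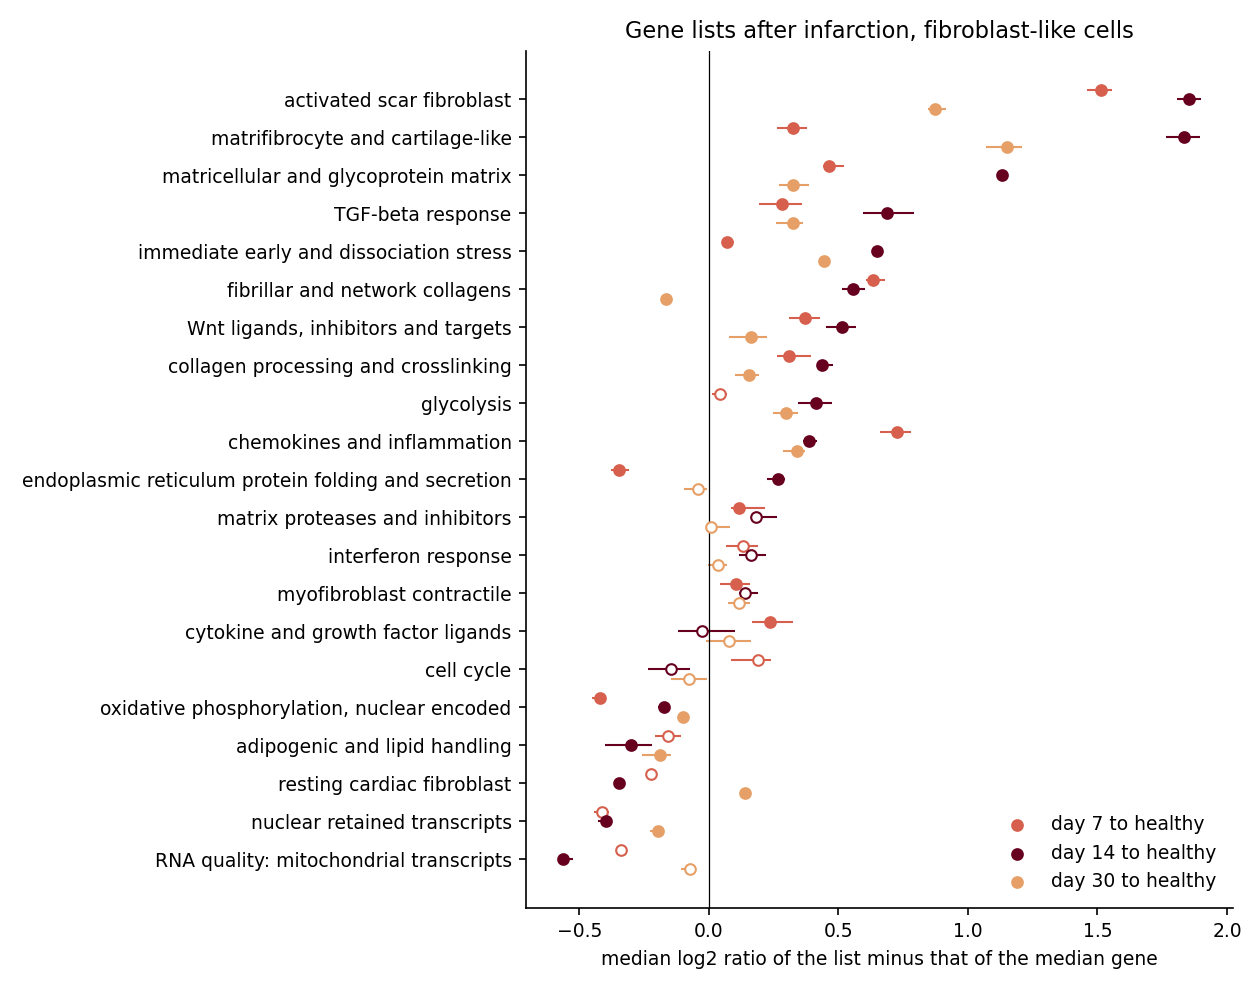
Median log2 ratio of each gene list to the healthy library, minus that of the median gene, for day 7, day 14 and day 30. Bars are 95% intervals from simulated counts; filled points lie outside the central 95% of 10000 expression-matched random lists and open points inside it, and the activated scar list is at 1.51, 1.85 and 0.87.

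The later libraries were also set against day 7. Compared with day 7, Comp was 8.98-fold higher (8.78 to 9.19) at day 14, the secreted protein gene Angptl7 8.15-fold (7.83 to 8.50), the transcription factor gene Maff 5.50-fold (5.197 to 5.83) and Sfrp2 5.33-fold (5.27 to 5.40). Matrifibrocyte genes had a median of 1.27 over day 7 (percentile 100, 9 of 14 above 1.5-fold), folding genes 0.44 (percentile 100, 13 of 31 above) and TGF-beta response genes 0.46 (percentile 100), with Id1 at 154 against 44.2 CPM. Lower at day 14 than at day 7 were the nuclear RNA Neat1 (3.95-fold, 3.85 to 4.06), the eotaxin gene Ccl11 (3.88-fold, 3.65 to 4.11), Col5a3 (3.59-fold, 3.41 to 3.78), Adamts5 (3.19-fold, 3.11 to 3.28) and Scara5 (3.16-fold, 3.03 to 3.30). Inflammatory genes were at -0.25 (percentile 0.02), with Saa3 at 0.471 CPM against 59.8, but with a minimum of 50 CPM this median was 0.07. Collagens were at -0.27 (percentile 0.01) and resting genes at -0.41 (percentile 0), with Cxcl14 at 211 against 597 CPM. The activated scar list was at 0.72 (percentile 100, 12 of 23 above 1.5-fold), crosslinking genes at 0.37 (percentile 99.98), matricellular genes at 0.31 (percentile 98.6) and mitochondrial transcripts at -0.38 (percentile 0.01).

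At day 30, Hk2 was 5.16-fold above its day 7 level (4.88 to 5.47), Angptl7 4.86-fold (4.65 to 5.07), Comp 4.67-fold (4.56 to 4.78), Lipe 2.80-fold (2.73 to 2.88) and the oxygenase gene Fmo2 2.49-fold (2.37 to 2.63). Collagens had a median of -0.66 against day 7 (percentile 0), with 13 of 19 more than 1.5-fold below the median gene. Col1a1 was 3.23-fold lower (3.19 to 3.27) and Col3a1 2.81-fold lower (2.79 to 2.84). The activated scar list was at -0.39 (percentile 0), with Lox at 39.4 against 140 CPM and Ptn at 134 against 447, although in adventitial Pi16-like cells alone it was at 0.22. Matrifibrocyte genes were at 0.63 (percentile 100, 8 of 14 above 1.5-fold) and oxidative phosphorylation genes at 0.32 (percentile 99.3). Lower were Wnt genes at -0.33 (percentile 0.04), inflammatory genes at -0.27 (percentile 0) and matricellular genes at -0.16 (percentile 0). Crosslinking genes at -0.14 (percentile 0.05), proteases at -0.12 (percentile 0.14) and contractile genes at -0.07 (percentile 0.77) were lower too. In adventitial Pi16-like cells alone the medians of the Wnt, matricellular, crosslinking and contractile lists were above 0. The Wnt median was also above 0 with a minimum of 50 CPM (0.0279), and the matricellular median without the genes that separate healthy and day 30 from day 7 and day 14 (0.0465). Those genes were picked by a gap that includes day 30 against day 7, so the matricellular value is no independent check. Scand1 (12.6-fold lower, 11.5 to 13.8), Eif3f (8.62-fold, 8.28 to 8.98), Nenf (5.11-fold, 4.95 to 5.28), the membrane protease gene Mmp14 (4.86-fold, 4.60 to 5.13) and Fam174a (4.77-fold, 4.43 to 5.14) were the genes that the naming rule, with its limit of 100 CPM, gave as lowest. Scand1, Eif3f, Nenf and Fam174a were at like levels in the healthy and day 30 libraries, and at like levels at day 7 and day 14. In all, 48 of 9251 measured genes were higher by more than 0.5 log2 units in both of the former than in both of the latter, and 396 were lower. The other 2 pairings of these 4 libraries gave 38 and 27 such genes, and 3 and 7.

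To describe the cells that held Cthrc1, those with 2 or more Cthrc1 UMIs after thinning were compared with those with 0 inside each infarct library. The classes held 766 and 7332 cells at day 7, 1703 and 4619 at day 14, and 160 and 5610 at day 30. The cytokine-like gene C1qtnf3 was 83.0-fold higher (63.6 to 110) in Cthrc1-positive cells at day 7, 27.0-fold (21.9 to 33.6) at day 14 and 19.1-fold (10.1 to 35.0) at day 30. The fibrillar collagen gene Col11a1 was 42.8-fold (29.3 to 64.0), 17.5-fold (12.1 to 26.1) and 62.2-fold higher (36.0 to 110) in the same order. Fmod was 17.3, 11.7 and 47.0-fold higher, Thbs4 17.1, 9.10 and 20.3-fold, Ddah1 32.8, 7.60 and 22.5-fold, and the osteopontin gene Spp1 26.1, 8.14 and 14.9-fold. Sfrp2 was 16.9, 5.61 and 7.68-fold higher, 1500015O10Rik 11.6, 6.46 and 19.3-fold, Fam101b 13.4, 6.61 and 15.6-fold, and Lmcd1 8.65, 6.86 and 7.95-fold. The smooth muscle gene Tagln was 10.7, 5.83 and 5.84-fold higher. Gm26771, at 14.2, 7.19 and 16.01-fold, overlaps the end of Sfrp2 on chromosome 3, so its counts can be shared with that gene and are uncertain.

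Scara5 was 32.3-fold lower (17.5 to 67.4) in Cthrc1-positive cells at day 7, 9.90-fold (6.75 to 15.1) at day 14 and 15.9-fold (4.39 to 131.5) at day 30. In the same order the glutathione transferase gene Gsta3 was 22.3-fold lower (13.3 to 40.8), 16.2-fold (12.3 to 21.8) and 10.8-fold (5.85 to 22.5), and Ces1d 17.1-fold (7.31 to 52.9), 26.02-fold (12.5 to 65.1) and 10.5-fold (2.91 to 87.2). Efemp1 was 19.0-fold lower (10.0 to 41.7), 11.7-fold (7.14 to 20.6) and 7.79-fold (2.655 to 37.8), and the chemokine gene Cxcl14 11.9-fold (9.71 to 14.7), 18.7-fold (14.6 to 24.4) and 9.38-fold (5.36 to 18.2). The dipeptidase gene Dpep1 was 10.9-fold lower (9.26 to 13.03), 9.67-fold (8.435 to 11.1) and 11.2-fold (7.87 to 16.5), and the cyclin gene Ccnd1 9.58-fold (6.185 to 15.7), 14.5-fold (9.12 to 24.6) and 12.5-fold (4.255 to 60.5). The last, 6030408B16Rik, was 11.8-fold lower (7.24 to 20.7), 11.9-fold (7.80 to 19.1) and 15.4-fold (4.26 to 127.6). At day 30 these intervals are wide, and for 5 of the 8 genes they span more than 10-fold. Of the resting fibroblast list, 22 of 24 measured members were lower in positive cells in each of the 3 libraries and 1 was higher in each. Of the activated scar list, 16 of 18 were higher in each and 0 lower. Of 18 collagens 13 were higher in each and 4 lower, and of 24 matricellular genes 18 were higher and 4 lower. Over all 2557 genes tested, 555 were higher in each library and 1077 lower. Of the inflammatory list, 12 of 14 were lower in each library. These libraries are 3 time points, not replicates, and the direction counts describe these cells.

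**Figure D3:**
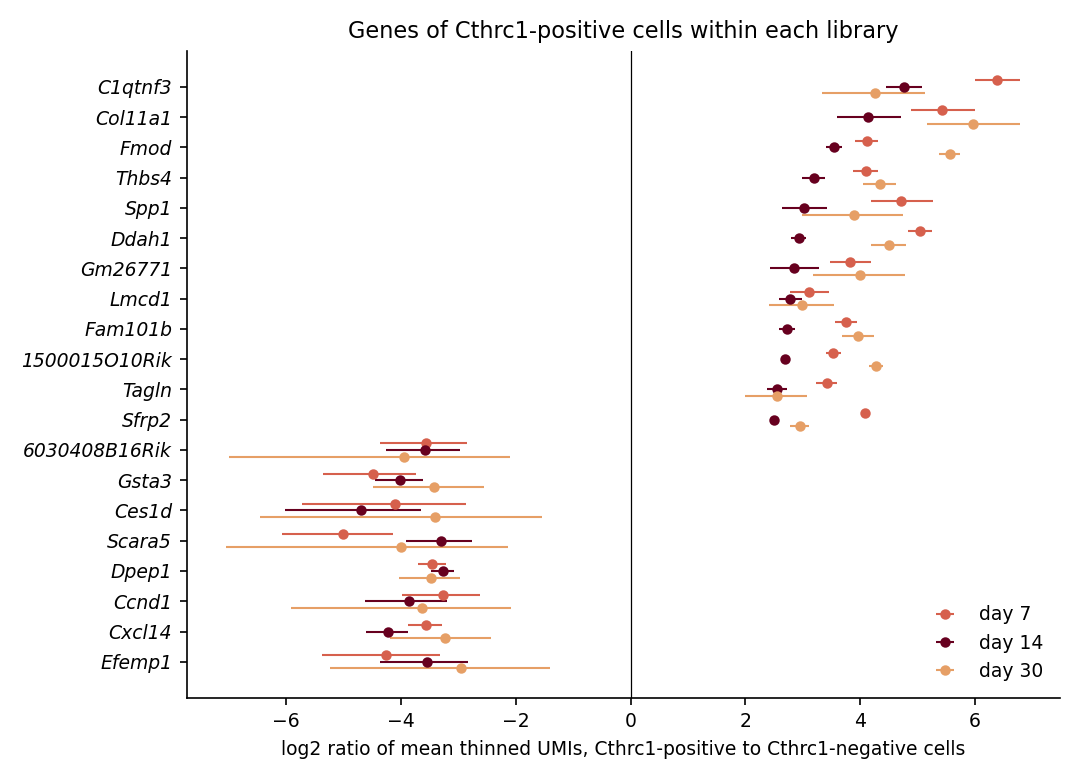
Log2 ratio of mean thinned UMIs in cells with 2 or more Cthrc1 UMIs to those with 0, for the 20 genes named by rule, in the day 7, day 14 and day 30 libraries. Bars are 95% intervals for counting error; C1qtnf3 is 83.0-fold higher and Scara5 32.3-fold lower at day 7.

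The knockout library was compared with the GFP library of the same day. Ucp2, a carrier of the inner mitochondrial membrane, was 20.2-fold higher (17.8 to 23.0) in the knockout library, the metalloproteinase inhibitor gene Timp1 8.55-fold (8.38 to 8.72), the calcium-binding protein gene S100a4 8.56-fold (8.23 to 8.91) and the smooth muscle actin gene Acta2 7.00-fold (6.80 to 7.21). The fibroblast transcription factor gene Tcf21 was 19.0-fold lower (17.6 to 20.5), at 24.1 against 458 CPM. The actin-severing protein gene Gsn was 8.55-fold lower (8.49 to 8.61), at 2754 CPM against 22638 to 32202 in the 4 GFP libraries. Cell cycle genes were higher, with a median of 1.53 log2 units above the median gene (1.46 to 1.60, percentile 100) and 13 of 20 members above 1.5-fold. Resting fibroblast genes were lower, at -0.86 (-0.91 to -0.80, percentile 0), with 14 of 24 more than 1.5-fold below. Within cycling cells, the only cluster with at least 100 cells of both libraries, these medians were 0.80 and -0.30. Over all fibroblast-like cells with no minimum expression level they were 0.66 and -1.41.

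The median gene itself was at -0.61 log2 units in the knockout library relative to day 7, and at -0.11 under median-of-ratios scaling, so list values are given relative to it. Oxidative phosphorylation genes had a median of 1.42 (1.39 to 1.43, percentile 100), with 25 of 31 above 1.5-fold, and 0.86 with no minimum expression level. Matched random lists spanned 0.01 to 1.14, so genes of like abundance also tended to lie above the median gene. The excess over such genes is smaller than 1.42, and the 25 of 31 was not set against a matched share. Atp5g3 was at 541 CPM against 188, Cox5a at 484 against 187 and Atp5g1 at 776 against 307. Of the cell cycle list, the microtubule regulator gene Stmn1 was at 361 CPM against 47.7, Cks2 at 185 against 24.4 and Ube2c at 60.9 against 3.24. Cycling markers summed to 381 CPM in fibroblast-like cells of the knockout library against 71.9 at day 7. Smooth muscle markers summed to 1260 CPM (of which Acta2 821 and Tagln 393) against 265, neutrophil markers to 17.6 against 1.09, and cardiomyocyte markers to 92.2 against 40.2 (Myl3 52.2 against 7.47). Contractile genes had a median of 1.08 at percentile 97.2, inside the random range of -0.32 to 1.10, with 11 of 17 above 1.5-fold, among them Tpm2 at 595 against 107 CPM and Myl6 at 3722 against 1284.

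Other genes higher in the knockout library were Fam221b (11.5-fold, 10.6 to 12.6), Hddc3 (9.64-fold, 8.78 to 10.6), the protease inhibitor gene Cst6 (8.46-fold, 8.14 to 8.78), the fatty acid-binding protein gene Fabp5 (6.59-fold, 6.29 to 6.91) and Grip2 (5.84-fold, 5.64 to 6.06). Other genes lower were the chemokine scavenger gene Ackr3 (15.1-fold, 13.7 to 16.7), the transferrin gene Trf (12.8-fold, 11.5 to 14.3), H2-T22 (11.4-fold, 10.2 to 12.8), Tmem100 (10.9-fold, 9.78 to 12.3) and Islr (8.39-fold, 8.00 to 8.79). Inflammatory genes had a median of -0.77 (percentile 0, 15 of 24 more than 1.5-fold below), with C1ra at 19.5 against 193 CPM and Tnfaip6 at 18.8 against 184. Stress and immediate early genes were at -0.46 (percentile 0.02, 12 of 24 below), with Socs3 at 76.0 against 819 CPM, Hspa1a at 41.3 against 411 and Junb at 518 against 4083. Interferon response genes were at -0.61 (percentile 0), with Ifit3 at 5.43 against 75.7 CPM. Proteases and inhibitors were at -0.73 (percentile 0.01), with Mmp3 at 2.23 against 97.55 CPM and Timp3 at 91.9 against 391.

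Matrix groups of the knockout library lay inside the range of random lists. Collagens had a median of 0.51 (percentile 59.3), matricellular genes 0.69 (percentile 66.1), crosslinking genes 0.20 (percentile 54.1), the activated scar list 0.55 (percentile 82.5) and matrifibrocyte genes 0.16 (percentile 38.9). Postn was at 1701 CPM against 1131 at day 7, Sparc at 13724 against 6612, Sfrp2 at 89.3 against 642 and Bgn at 2248 against 5008. Col1a1 was at 2629 against 2608 CPM and Col3a1 at 3758 against 4262, and the order of Col3a1 turns when taken relative to the median gene. Also inside were TGF-beta response at 0.15 (percentile 48.2), Wnt genes at 0.15 (percentile 61.6), glycolysis at 0.07 (percentile 39.2), folding genes at 0.34 (percentile 23.0) and ligands at 0.02 (percentile 55.9). Lipid handling at -0.31 (percentile 5.58), mitochondrial transcripts at 0.56 (percentile 43.0) and nuclear retained transcripts at -0.52 (percentile 5.34) completed this group. Clusters with at least 100 cells of both libraries were limited to cycling cells, with 275 knockout and 140 day 7 cells, so cells of 1 type could hardly be compared across the pair. Predicted genes and pseudogenes took 1.87% of the knockout counts against 0.841% at day 7, with Gm10260, chosen after its values were seen, at 1117 against 29.3 CPM.

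Cells called activated scar-like by their markers made up 0.0152% of the healthy library (0.000384 to 0.0845), 12.7% of day 7 (11.99 to 13.3), 44.1% of day 14 (43.0 to 45.2), 0.831% of day 30 (0.623 to 1.09) and 19.1% of the knockout (17.95 to 20.3). They sat in cluster 9 at day 7, cluster 3 at day 14 and cluster 11 in the knockout. Each of these clusters came mostly from 1 library and had its own leading genes, so the shares are given per library and not compared. They also turned on the clustering: the day 14 share was 1.56% at resolution 1 and 0% with that library clustered alone, the day 30 share 15.4% at resolution 0.3, and the knockout share 0.0874% at resolution 0.3. Cells in unnamed fibroblast-like clusters made up 84.7%, 41.7%, 11.7%, 85.4% and 72.7% in the order healthy, day 7, day 14, day 30 and knockout. Interstitial resting-like cells made up 0.0758%, 31.8%, 31.0%, 0.690% and 0% in the same order. Both shares set healthy and day 30 apart from day 7 and day 14, so they are not read as changes of cell state. With each library clustered alone, the interstitial resting name went to 1184 cells at day 7, 1493 at day 30 and clusters of 1129 and 829 knockout cells. No cluster of the healthy or day 14 library took it, so these shares, the 0% included, depend on the clustering. Of the unnamed knockout cells, 3193 sat in cluster 5, where 99.9% of cells came from that library. Inside the activated scar-like class, Cthrc1 was at 1998 CPM (1967 to 2030) at day 7, 1541 (1526 to 1556) at day 14, 1139.7 (1037 to 1250.2) at day 30 and 116 (109 to 123) in the knockout.

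**Figure D4:**
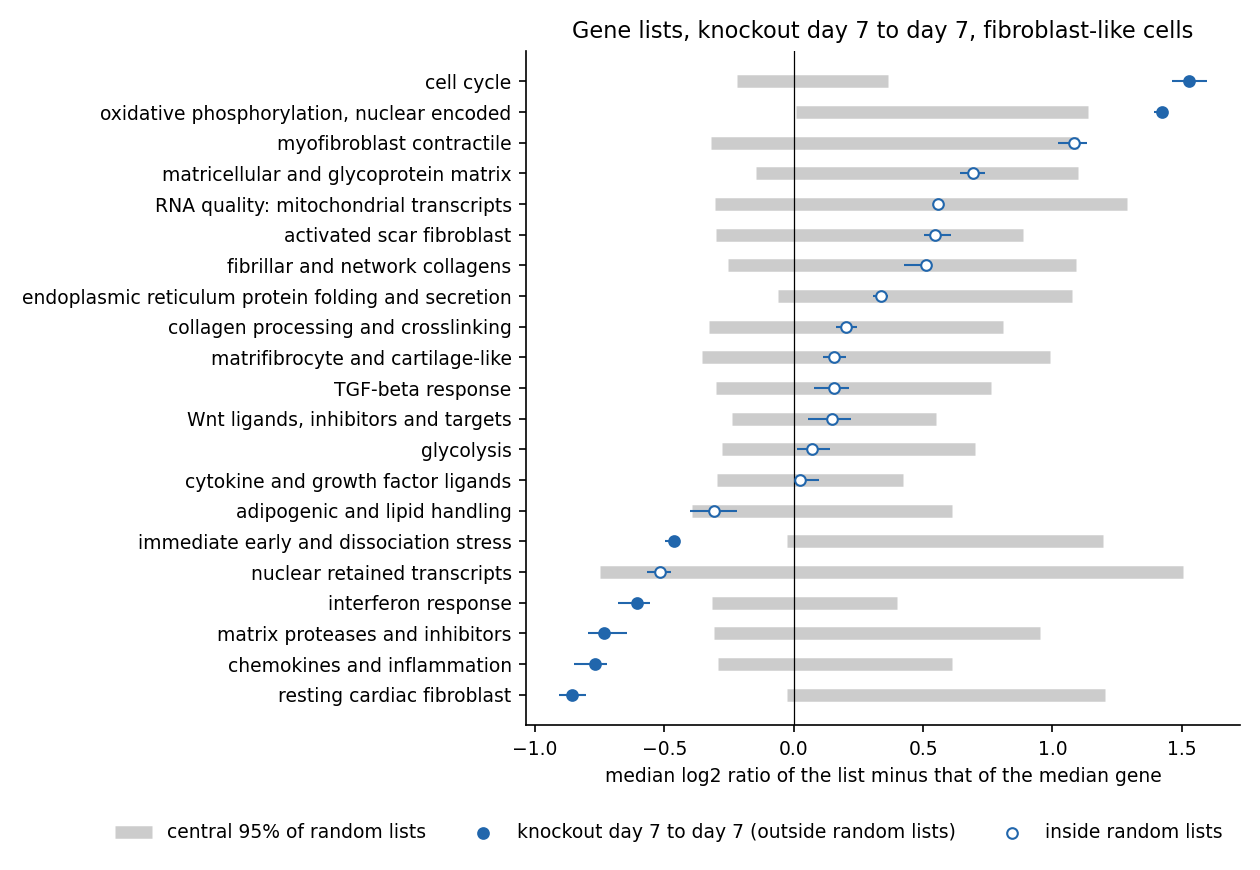
Median log2 ratio of each gene list in the knockout library against day 7, minus that of the median gene. Grey bars span the central 95% of 10000 expression-matched random lists, blue bars are 95% intervals from simulated counts, and filled points lie outside the grey range, from 1.53 for cell cycle to -0.86 for resting fibroblast genes.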

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

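The tests of transcript length, of abundant genes, of named genes near Cthrc1 and of the GC content of genes higher in healthy and day 30 were chosen only after the results were seen, and the split of the libraries was itself found in the data. List medians differed between time points in opposite directions, and none of these differences was tested. The collagen median relative to healthy was 0.80 log2 units higher at day 7 than at day 30 and 0.72 higher at day 14 than at day 30. The resting fibroblast median was 0.48 higher at day 30 than at day 14, and the folding list was 0.61 higher at day 14 than at day 7.

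Cthrc1 was also counted outside the fibroblast-like cells on which the comparisons between libraries rest. In mesothelial-like cells it stood at 285 CPM at day 7 and 703 at day 14, above the 20.6 CPM of the healthy library and its upper limit of 74.5. In pericyte-like cells it stood at 63.5 CPM at day 7 and 43.8 at day 14, above 0 in the healthy library and its upper limit of 13.3. The pericyte-like counts served as a guide to free RNA and are not read as expression. At day 7, interstitial resting-like cells stood at only 19.3 CPM (17.4 to 21.4), so evenly spread free RNA does not give the pericyte-like level. At day 14 they stood at 37.2 CPM, inside the pericyte-like interval of 28.3 to 64.7. The mesothelial-like level of that library, 703 CPM (667 to 741), lay far above both. After thinning, 62 of 180 mesothelial-like cells (34.4%) held a Cthrc1 UMI there. Evenly spread free RNA therefore does not give the mesothelial-like level at day 14. What gives the pericyte-like level at day 7 and the mesothelial-like levels was not tested.

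The named genes that set the knockout library apart from day 7 were measured in mesothelial-like cells too, 62 in the knockout library and 37 at day 7. Their median size there was 0.845 (0.761 to 0.917) of that in fibroblast-like cells, over 23 measurable genes. Genes entered with 10 or more UMIs summed over both libraries in mesothelial-like cells, so genes high in the knockout could enter through it alone. These cells held 890496 UMIs in the knockout against 249106 at day 7, so day 7 counts were low. The value therefore does not decide whether the difference runs through the library. Sort marker, reporter and genotype are confounded as well. The difference was far smaller in mesothelial-like than in fibroblast-like cells for Acta2 (0.25 against 2.76 log2 units), Fabp5 (0.59 against 2.59), Stmn1 (0.66 against 2.80), Ucp2 (0.94 against 3.44) and Tpm2 (1.07 against 2.42). Genes within 10 Mb of Cthrc1 made up 0.478% (0.206 to 0.939) of those more than 2-fold from the median gene, against 0.432% of all measured genes. The 40 measured genes there keep this share low in any case. Of the 24 named genes 0 lie there, so none of the named differences is that of a gene held by this DNA. With so few measured genes there, 0 was likely whatever the cause. In the same stretch 8 genes were more than 2-fold from the median gene, so effects of flanking DNA on the genes it holds stay open. A larger share of a few abundant genes would move all others by 1 shift, but 22.3% (21.4 to 23.1) of the 9201 measured genes outside the 50 most abundant lay over 2-fold from the median gene by their whole counting interval, 1545 above and 504 below, which argues against it as the only cause, although this was test 3 of that explanation, after 2 on named genes, whose choice fixed the outcome.

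Genes such as Scand1, Eif3f, Nenf, Wdr89 and Cox17 separate healthy and day 30 from day 7 and day 14. The gap between healthy and the day 7 and day 14 libraries was 1.19 times (1.18 to 1.32) as large in pericyte-like cells as in fibroblast-like cells, over 414 genes. Genes entered with 10 or more UMIs summed over these libraries in pericyte-like cells, so genes high at day 7 and day 14 could enter through those alone. Healthy pericyte-like cells held 278210 UMIs against 834324 and 570807, so their counts were low. The value therefore does not decide whether activation of fibroblasts alone gives the split. Day 30, with 14 pericyte-like cells, was left out and is open. Of the 396 genes higher at day 7 and day 14, the 395 with an annotated sequence were at percentile 0.08 for transcript length, shorter where a length bias needs longer, and at percentile 64.4 for GC content of the 3′ end. The 48 genes higher in healthy and day 30 were at percentile 0 for length and 99.7 for GC content, so both stay open for these genes. Processing batch is not given in the labels and was not tested.

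Cthrc1 UMIs in the knockout library were not spread evenly over cells. Cthrc1 was 25.3 times (20.4 to 31.7) as high in the 873 activated scar-like cells as in the 3600 other fibroblast-like cells of that library, 116 against 4.59 CPM. Free RNA would be expected to be even, so it does not account for most of these UMIs. Whether they come from a transcript of the altered gene was not tested.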

How the results depend on the processing

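The alternatives using adventitial Pi16-like cells alone, activated scar-like cells alone, no predicted genes in the clustering, or no genes that separate healthy and day 30 from day 7 and day 14 were chosen only after the results were seen. No paired analysis was possible because each group had 1 library and no test was run. Of 71 list medians outside the random range, 68 kept their direction under every alternative set beforehand, and 10 changed it under some alternative, those added later included. Direction means the sign relative to the median gene. No alternative was placed again among random lists, so whether the calls hold was not tested. Of all list values under alternatives, 667 of 1638 moved out of the counting interval of the main value, as did 1013 of 3402 for named genes. Where a value below differs from the report, the cause was not tested. The separating genes were chosen by differences between these same libraries, so leaving them out tends to shrink those differences and is no independent check.

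The Cthrc1 ratio to healthy ranged from 64.8 to 75.5 at day 7, 174 to 190 at day 14 and 17.0 to 19.9 at day 30 under the alternatives set beforehand. In adventitial Pi16-like cells alone it was 4.69, 12.6 and 3.33, with no background subtracted. The day 7 level there, 28.1 CPM, lay below the 63.5 CPM of pericyte-like cells and above the 19.3 CPM of interstitial resting-like cells. The knockout ratio to day 7 was 0.196 under median-of-ratios scaling, 0.130 without mitochondrial and ribosomal protein genes, 0.0880 as a mean over cells, 0.165 with clusters compared separately (cycling cells only) and 0.0581 in activated scar-like cells alone.

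The activated scar median at day 7 was 1.43 with the stricter cell filter, 1.46 as a mean over cells, 0.95 with a pseudocount of 20 CPM, 1.58 with a minimum of 50 CPM, 0.43 in adventitial Pi16-like cells alone and 1.04 without the genes that separate the libraries. At day 14 it was 1.94 without mitochondrial and ribosomal protein genes, 1.77 as a mean over cells, 2.51 and 1.36 with pseudocounts of 1 and 20, 1.78 with no minimum, 2.17 with a minimum of 50, 0.98 in adventitial Pi16-like cells and 1.11 without separating genes. At day 30 it was 0.96 and 0.74 with pseudocounts of 1 and 20, 0.82 with no minimum, 0.95 with a minimum of 50 and 0.73 in adventitial Pi16-like cells.

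The matrifibrocyte median at day 14 was 2.09 with all cells, 2.03 and 1.31 with pseudocounts of 1 and 20, 1.35 with no minimum, 1.98 with a minimum of 50, 1.13 in adventitial Pi16-like cells and 2.29 without separating genes. At day 30 these were 1.43, 1.26, 0.67, 0.64, 1.24, 0.84 and 1.43.

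In the knockout against day 7, the resting fibroblast median was -0.70 under median-of-ratios scaling, -0.53 as a mean over cells, -0.75 and -0.91 with pseudocounts of 1 and 20, -1.41 with no minimum, -1.11 with a minimum of 50, -0.30 with clusters separate (cycling cells only) and -0.70 in activated scar-like cells. The cell cycle median was 1.64 under median-of-ratios scaling, 1.60 without mitochondrial and ribosomal protein genes, 1.39 as a mean over cells, 1.82 and 1.02 with pseudocounts of 1 and 20, 0.66 with no minimum, 1.20 with a minimum of 50 and 0.80 with clusters separate (cycling cells only). The oxidative phosphorylation median in the same order was 1.61, 1.49, 1.38, 1.61, 1.10, 0.86, 1.10 and 1.17, and 1.56 in activated scar-like cells.

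In all, 13 list values changed direction. In adventitial Pi16-like cells alone these were contractile genes at day 7 (-0.20), collagens at day 14 (-0.24) and resting genes at day 14 (0.18), and for day 30 against day 7 matricellular (0.0952), crosslinking (0.16), contractile (0.0865), activated scar (0.22) and Wnt genes (0.0751). Without separating genes they were collagens at day 14 (-0.16) and matricellular genes for day 30 against day 7 (0.0465), where the genes left out were picked by these same differences. With no minimum, Wnt genes at day 30 against healthy were at -0.0084. With a minimum of 50 CPM, inflammatory genes for day 14 against day 7 were at 0.0730 and Wnt genes for day 30 against day 7 at 0.0279.

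The share of cells with a Cthrc1 UMI, in the order healthy, day 7, day 14, day 30 and knockout, was 0.406%, 10.6%, 27.8%, 4.24% and 2.303% after thinning to 1000 UMIs, and 1.67%, 18.2%, 51.8%, 11.9% and 10.4% unthinned. With at least 2 UMIs it was 0.0491%, 9.04%, 23.5%, 2.66% and 0.447%. With the stricter filter it was 12.7% at day 7. Thinned to 1000 UMIs, 6030408B16Rik and Ces1d had 0 UMIs in 82 positive cells at day 30 and so no ratio.

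The share of activated scar-like cells depended strongly on clustering. In the healthy library it was 0.303% at resolution 0.3, 0% at resolution 1, 5.005% with the library clustered alone and 0% without list genes. At day 7 it was 11.7% at resolution 1 and 11.3% with 1000 variable genes. At day 14 it was 45.6% at resolution 0.3, 1.56% at resolution 1, 1.36% with 1000 variable genes and 0% alone. At day 30 it was 15.4% at resolution 0.3, 0.125% at resolution 1, 0.0940% with 1000 variable genes, 15.7% alone, 0.549% without list genes and 0.517% without predicted genes. In the knockout it was 0.0874% at resolution 0.3, 17.5% at resolution 1, 16.4% without list genes, 16.9% with the stricter filter and 15.6% without predicted genes.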

Other observations

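No explanation was tested for the values below, all of which were picked out after the data were seen. Schwann cell and glial markers in fibroblast-like cells summed to 509, 464, 476 and 576 CPM in the healthy, day 7, day 14 and day 30 libraries and to 175 in the knockout, most of it from Gpm6b. Mesothelial markers summed to 273, 579.8, 219, 398 and 141 CPM, most of it from the complement gene C3. General fibroblast markers summed to 37342 CPM in the knockout against 63164 to 71261 in the other 4 libraries. Most of the gap to day 7 lay in Gsn (2754 against 23553 CPM) and Dcn (14369 against 19196).

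Mesothelial-like cells made up 0.318% of the healthy library, 0.395% of day 7, 2.34% of day 14, 3.18% of day 30 and 1.36% of the knockout. With each library clustered alone, 14, 30, 187, 38 and 63 cells took this name in the same order. At day 30 the joint clustering gave 203 such cells, so that share depends on the clustering. Cells in the interferon-response cluster made up 1.53%, 2.16%, 2.88% and 1.93% of the 4 GFP libraries and 0 of 4575 cells in the knockout. With the knockout library clustered alone, 42 of its cells formed a cluster with these markers, so the 0 depends on the joint clustering.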
